A study of Mus musculus with 1055 samples.

How the data were processed

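The series holds Smart-seq2 libraries with Nextera indexing of 1055 single cells on 7 plates, 1 column per cell. Cells were Hoechst-negative and tdTomato-positive and came from the dentate gyrus of mice that were 7 to 8 weeks old when injected with tamoxifen. The mice carried Gli1-CreERT2 or Ascl1-CreERT2 with a tdTomato reporter and were dissected 5 days or 12 weeks after the last injection. The groups were Gli1 at 5 days (135 cells, plates G5a with 55 and G5b with 80), Ascl1 at 5 days (237, plate A5), Gli1 at 12 weeks (186, plate G12) and Ascl1 at 12 weeks (233, plates A12a with 57 and A12b with 176). The title and the time label of a further plate (AX, 264 Ascl1 cells) disagreed, so it was clustered with the others, joined no group and was added to either Ascl1 group only as an alternative. The labels name no mouse for a cell, and no mapping to animals was attempted. The titles of 5 plates carry a string that reads as a date, a different one for each, and those of A12a and AX carry none, so no date held more than 1 group, and date and group cannot be told apart.

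As deposited, the table holds for each cell the natural log of 1 plus the reads of a gene per 10000 reads of that cell over the genes in the table, although its name speaks of counts. The labels name cutadapt 1.16, STAR 2.6.0c, Seurat 3.0.2, R 3.6.1 and GRCm38 for processing by the authors, with no role or order, and do not state how cells and genes were filtered. Back-transformed values summed to 10000 in every cell, and all of them were whole multiples of the value of 1 read within 0.05 reads, so the reads of each gene and the total of each cell were recovered. The 15515 rows included 154 genes without a read and 23 names that a spreadsheet had turned into dates, with 2 of these names on 2 rows each. These names were kept and no gene was named from them. Xist, Npas4, Sst, Pvalb, Foxj1 and Icam5 were among list members absent from the table, as were the reporter and Cre. Raw reads were not used here.

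Cells had from 50552 to 1798839 recovered reads (median 221648) and from 1086 to 5766 genes (median 3503). The groups held 55621679 (Gli1, 5 days), 44714558 (Ascl1, 5 days), 75919392 (Gli1, 12 weeks) and 56425709 reads (Ascl1, 12 weeks). A floor of 3 reads over a group was used where a gene or a share had a count of 0. Shares carry exact Clopper-Pearson intervals and summed reads exact Poisson intervals at 95%, ratios to 1 to 3 reads carry exact conditional binomial intervals, and all of these cover counting error only.

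Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Cells with at least 1000 genes were kept, which removed 0 cells. Clustering used log2(CPM+1), genes read in at least 5 cells, 2000 variable genes chosen within plates without Gli1, Ascl1, sex-linked and mitochondrial genes, 30 principal components, 15 neighbours and Leiden resolution 1. Clusters were named from 14 marker lists fixed before the files were seen. The naming rule itself was set after the data had been seen, in 3 forms. Marker scores over all cells named 1 large cluster of G12 microglia-like. Scores centred within plates, with the best class required to have 3 markers read in at least 10% of the cells, left neuroblast clusters of alternative clusterings without a name. The form used takes the highest plate-centred mean score among classes with at least 3 markers read in at least 10% of the cells and requires a score of at least 0.05 and a median gene number of at least 0.5 times that of all cells. Clusters that alternative clusterings named granule neuron-like were joined to neuroblast-like ones, and kept apart in an alternative added later. The last 2 forms gave the same classes for the clustering reported. Stem-like and astrocyte markers fell into 1 cluster, so comparisons planned for stem-like cells were made in this astroglia-like class. Astroglia-like cells numbered 69, 10, 21 and 24, cycling cells 21, 66, 18 and 27, and neuroblast-like cells 43, 161, 147 and 176 in the group order given above. No doublet caller was run.

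Within a class the reads of a group were summed and scaled to CPM by their total, and log2 ratios used a pseudocount of 1 CPM. For each of 19 gene lists fixed in advance, the median log2 ratio was taken over members at 20 CPM or more in at least 1 group and read in at least 25% of its cells. It was ranked among 10000 random lists of the same size drawn from 20 bins of expression. A list was called where at least 3 members were left, its median lay outside the middle 95% of random lists (percentiles 2.5 and 97.5) and every pair of plates with at least 10 class cells gave the same sign. In astroglia-like cells the drivers at 12 weeks and the Ascl1 times had 1 such pair each, with nearly all of their cells. The sign rule therefore added little there. Setting genes with 0 reads in a group to their bound left the median of every called list as it was. At least 10 astroglia-like or 20 neuroblast-like cells per group were required. From each list the 2 highest and 2 lowest members were available for naming. Single genes were named by a rule fixed before the files were seen: past the same expression floor, a log2 ratio of at least 1 in size and the same direction in every such pair of plates, with the 10 highest and 10 lowest in astroglia-like cells and 5 each in neuroblast-like cells. Unnamed gene models, mitochondrial, ribosomal and sex-linked genes were left out. Gli1 and Ascl1 were always given. Gene coordinates are those of GENCODE vM21 on GRCm38. For cycle genes every cell was thinned to 50000 reads, and the planned background class of granule neuron-like cells was replaced by neuroblast-like cells because no cluster was named granule neuron.

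No test between groups was made. Each group counted as 1 sample because no label names the animals of a cell or a plate, and plates were not taken as replicates. Between G5a and G5b, 26.9% of genes at the floor in astroglia-like and 37.3% in neuroblast-like cells differed at least 2-fold. Between A12a and A12b 27.9% did so in neuroblast-like cells. The single-gene rule and the range of random lists, but not the sign rule for lists, were tested on simulated data of the same group sizes. Both simulated groups were drawn from 1 common mean, so the simulated shares leave out such differences between plates. There, 34.3%, 32.0%, 23.6% and 39.1% of unchanged genes passed the single-gene rule in the astroglia-like comparisons and 11.6%, 3.64%, 13.5% and 2.45% in the neuroblast-like ones. Of genes changed 4-fold, 72, 83, 89 and 86% passed in astroglia-like and 97, 94, 100 and 100% in neuroblast-like cells, and from 1.5 to 6% of random lists of 20 unchanged genes lay outside the middle 95%. Simulated genes varied independently, so this last share does not hold for lists whose members vary together. Between plates of the same group most lists lay inside their random range, but some did not. Oxidative phosphorylation genes lay outside it in astroglia-like (G5a against G5b, median -0.44) and neuroblast-like cells (-0.51, and 0.52 for A12a against A12b). Alternatives covered clustering resolutions 0.5 and 2, 1000 variable genes, variable genes over all cells, at least 2000 genes per cell, classes from the marker score of each cell, mean CPM over cells, a pseudocount of 5, no floor or one of 50 CPM, TMM and median-of-ratios scaling, thinning to 20000 reads or none, 2 reads or more, each plate of a pair left out, and AX added to either group. TMM and median-of-ratios scaling were written in numpy from their published definitions, and edgeR and DESeq2 were not used.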

Results

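Single tdTomato-positive cells were sorted from the dentate gyrus of adult mice that carried a tamoxifen-inducible Cre recombinase (CreERT2) under the control of Gli1 or of Ascl1. Cre switched on a tdTomato reporter permanently in the recombined cell and its progeny. Gli1 is a transcription factor and target of Hedgehog signalling, and Ascl1 is a proneural transcription factor of activated stem cells and progenitors. Cells were taken 5 days or 12 weeks after the last tamoxifen injection, and the polyadenylated RNA of each cell was read by Smart-seq2, a plate-based method that covers whole transcripts. Each driver at each time made up 1 group, and the 4 groups held 791 cells. The Gli1 cells at 5 days came from 2 plates, G5a with 55 cells and G5b with 80. The Ascl1 cells at 12 weeks also came from 2, the small plate A12a with 57 cells and the larger A12b. The other groups came from 1 plate each, A5 for Ascl1 at 5 days and G12 for Gli1 at 12 weeks. A further plate of Ascl1 cells, called AX here, had labels that disagreed on its time point and joined no group. The median depth per cell was 280193 reads for Gli1 and 190316 for Ascl1 at 5 days, and 407160 and 206928 at 12 weeks. Single cells ranged from 50552 to 1798839 reads and from 1086 to 5766 detected genes. No label tied a cell to a mouse, so each group counted as 1 sample, without replicates. No error between animals could be given and no test between groups was made. No plate held more than 1 group, so driver and time cannot be told apart from plate in any comparison. Intervals are exact 95% intervals, and together with the limits given for counts of 0 they cover counting error only. Reads copied by PCR without molecular identifiers are not independent molecules, so the true counting error is larger. A fold given as at least a value takes reads as the unit and leaves out variation between cells. It describes the reads of the sampled cells and is not a lower limit on a difference between groups. Expression levels are reads summed over the cells of a class in a group, scaled to all reads of those cells (CPM).

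Graph-based clustering of all 1055 cells gave 9 clusters, which marker genes fixed in advance sorted into 3 classes and 1 cluster of 15 cells without a name. The astroglia-like class was 1 cluster with the markers of quiescent radial glia-like stem cells and of astrocytes together. Hopx, a homeodomain protein of quiescent dentate stem cells (chromosome 5, 77086988 to 77115121, minus strand, GRCm38), was read in 96.6% of them at 648 CPM, against 67.5 CPM in cycling and 5.22 CPM in neuroblast-like cells. Aqp4, the water channel of astrocytes (chromosome 18, 15389496 to 15410982, minus strand), was read in 40.4% of them at 186.1 CPM, and Itih3 and Fgfr3, further astrocyte markers, stood at 770 and 443 CPM. The scores for astrocytes and stem cells in this cluster were 1.02 and 0.654, and no clustering step separated them, so these identities are described together. The cycling progenitor-like class joined 2 clusters. Top2a, the topoisomerase that untangles replicated DNA, stood there at 316 CPM and the proliferation marker Mki67 at 211.2 CPM, against 1.1597 and 0.0814 CPM in astroglia-like cells. Neuroblast-like cells were the largest class, with 708 of the 1055 cells. Neurod1, a transcription factor of young granule neurons (chromosome 2, 79452521 to 79456751, minus strand), was read in 95.9% of them at 827 CPM. The microtubule protein gene Dcx was read in 78.8% of them at 382 CPM and Calb2 in 72.9% at 506 CPM. Calb1, the calbindin gene of mature granule neurons, stood at 1.60 CPM there. In this clustering no cluster was named granule neuron, although the largest neuroblast-like cluster scored 0.149 for neuroblast against 0.143 for granule neuron markers. At resolution 2, and with variable genes chosen over all cells, some clusters were named granule neuron-like.

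Class shares asked which kinds of labelled cell each driver gave at each time. At 5 days, astroglia-like cells made up 51.1% of the Gli1 group (69 cells, interval 42.4 to 59.8%) and 4.22% of the Ascl1 group (10 cells, 2.04 to 7.62%). Cycling progenitor-like cells made up 15.6% of the Gli1 cells (9.89 to 22.8%) and 27.8% of the Ascl1 cells (22.2 to 34.02%). Neuroblast-like cells made up 31.9% (24.1 to 40.4%) and 67.9% (61.6 to 73.8%). At 12 weeks both drivers had given mainly neuroblast-like cells, 79.03% for Gli1 (72.5 to 84.6%) and 75.5% for Ascl1 (69.5 to 80.9%). Astroglia-like cells then made up 11.3% of the Gli1 cells (7.13 to 16.7%) and 10.3% of the Ascl1 cells (6.71 to 14.9%), and cycling cells 9.68% (5.84 to 14.9%) and 11.6% (7.78 to 16.4%). For these 3 classes the intervals of the drivers overlapped at 12 weeks in this clustering, but for neuroblast-like cells this did not hold under other ways of naming cells. The unnamed cluster took 1.48% of the Gli1 cells at 5 days and 2.58% of the Ascl1 cells at 12 weeks. It held 0 Ascl1 cells at 5 days and 0 Gli1 cells at 12 weeks, which allows shares of up to 1.27% and 1.61%. Within groups the plates differed, with astroglia-like shares of 60% in G5a and 45% in G5b, and of 1.75% in A12a and 13.1% in A12b. When each cell was named by its own marker score instead, 0.538% of the Gli1 and 51.5% of the Ascl1 cells at 12 weeks were neuroblast-like, and with cluster scores not centred within plates 12.9% and 67.8% were. With granule neuron-like clusters of resolution 2 kept apart, neuroblast-like cells made up 43.04% (Ascl1, 5 days), 26.9% (Gli1, 12 weeks) and 41.6% (Ascl1, 12 weeks).

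**Figure D1:**
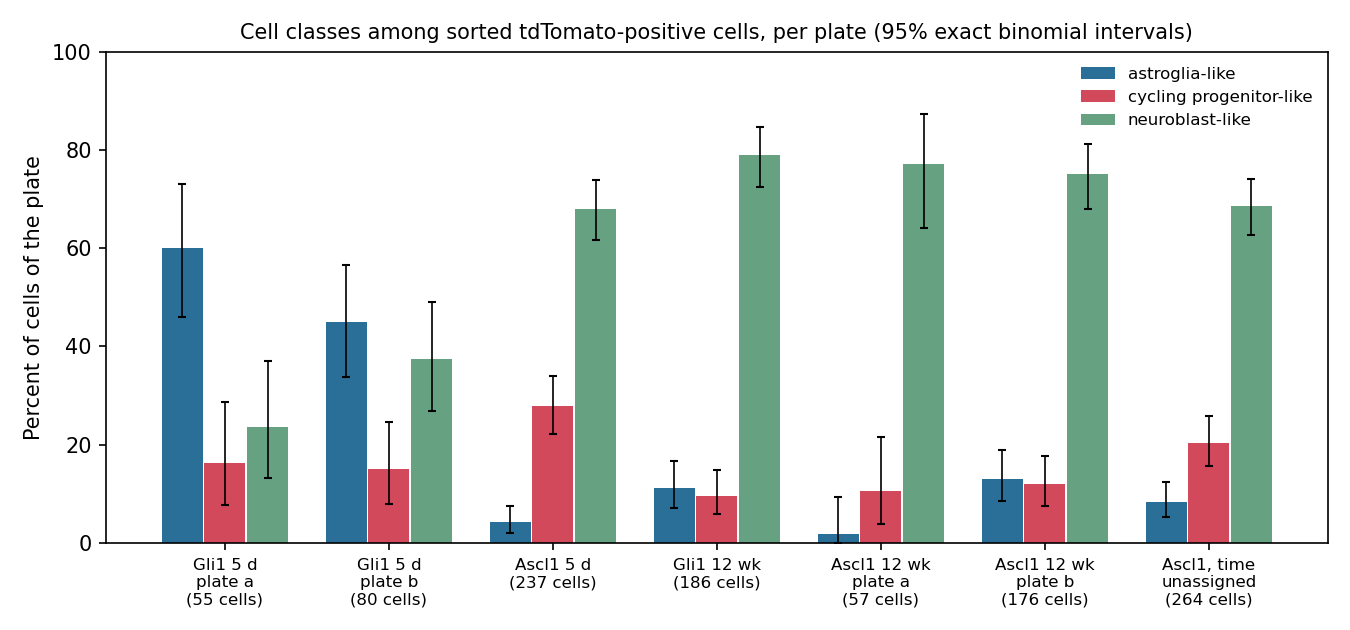
Share of the cells of each plate (percent) that fell into the astroglia-like, cycling progenitor-like and neuroblast-like classes, with exact 95% intervals as bars. Astroglia-like cells reached 60% and 45% in the Gli1 plates at 5 days and 13.1% or less in every other plate.

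Reads of the cycle genes Mki67 and Top2a were counted to see how many labelled cells were dividing, after each cell was thinned to 50000 reads. At least 1 such read was found in 24.5% of the Ascl1 cells at 5 days (58 cells, 19.1 to 30.5%) and in 8.15% of the Gli1 cells (11 cells, 4.14 to 14.1%). By 12 weeks the shares were 3.86% for Ascl1 (9 cells, 1.78 to 7.21%) and 4.30% for Gli1 (8 cells, 1.87 to 8.30%). Most of these cells belonged to the cycling class, for which both genes were among the 10 naming markers, and in which 75.8% of the Ascl1 cells and 42.9% of the Gli1 cells had a read at 5 days, and 29.6% and 33.3% at 12 weeks. Granule neuron-like cells, planned as a class that should lack such reads, were replaced by neuroblast-like cells because no cluster was named granule neuron. Neuroblast-like cells had a read in 4.35% (Ascl1) and 4.65% (Gli1) at 5 days and in 0.568% and 1.36% at 12 weeks. Whether some of these neuroblast-like cells were dividing was not tested, so the shares are not a pure background. Median depths before thinning were 186309, 261996, 202466 and 396877 reads in these cells, and 200468, 320881, 172110 and 478558 reads in the cycling class. In astroglia-like cells a read was found in 0 of 69 Gli1 cells at 5 days, which allows a share of up to 4.35%, and in 1 of 10 Ascl1 cells. At 12 weeks it was found in 0 of 21 Gli1 and 0 of 24 Ascl1 cells (up to 14.3% and 12.5%). The plates of a group stood at 9.09% (G5a) and 7.50% (G5b), and at 0 of 57 cells (A12a) and 5.11% (A12b). Without thinning the Gli1 share at 12 weeks was 8.60%, with 2 reads or more required it was 1.61%, and with plate AX added the Ascl1 share at 12 weeks was 8.65%.

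Transcripts of the driver genes themselves were counted because the Cre allele of each line sits at that gene. Gli1 (chromosome 10, 127329882 to 127341974, minus strand) was read in astroglia-like cells of 4 of 4 groups, with reads in 14.5% of the Gli1 cells (10 of 69, 7.17 to 25.04%) and 1 of 10 Ascl1 cells (0.253 to 44.5%) at 5 days. At 12 weeks it was read in 9.52% (2 of 21, 1.17 to 30.4%) and 33.3% (8 of 24, 15.6 to 55.3%). The summed level there was 10.7, 21.3, 21.9 and 59.7 CPM in the same order. In cycling cells Gli1 was read in 1 of 21 Gli1 and 8 of 66 Ascl1 cells at 5 days (0.0942 and 10.03 CPM) and in 2 of 18 and 4 of 27 at 12 weeks (0.249 and 15.4 CPM). No Gli1 read was found in neuroblast-like cells of the 4 groups, which allows shares of up to 6.98% (Gli1) and 1.86% (Ascl1) at 5 days and of up to 2.04% and 1.70% at 12 weeks. In plate AX 0.552% of the neuroblast-like cells had a Gli1 read. Ascl1 (chromosome 10, 87490819 to 87493660, minus strand) was read in 66.7% of the astroglia-like Gli1 cells and 50% of the Ascl1 cells at 5 days, and in 42.9% and 62.5% at 12 weeks. In cycling cells it was read in 52.4% and 66.7% at 5 days and 72.2% and 55.6% at 12 weeks, and in neuroblast-like cells in 9.30%, 6.83%, 4.76% and 4.55%. In astroglia-like cells the summed Ascl1 level was 178.05 CPM (Gli1) and 111.5 CPM (Ascl1) at 5 days, and 64.8 and 88.1 CPM at 12 weeks.

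Metabolic and stress gene lists were compared between classes within each group, although the plates of a group entered the classes in different shares. Astroglia-like cells had more reads of glycolysis genes than neuroblast-like cells in 4 of 4 groups (3.20 to 5.49-fold), with 19275 against 3753 CPM in the Gli1 cells at 5 days. Genes of fatty acid oxidation were higher by 2.19 to 3.44-fold, of lipogenesis by 2.55 to 4.73-fold, of cholesterol synthesis by 1.18 to 1.74-fold, and of the interferon response and MHC class I by 2.52 to 4.89-fold. The lipogenesis list holds Thrsp, also a stem cell marker used to name clusters, which made up most of its reads in the astroglia-like Gli1 cells at 12 weeks. The lipogenesis contrast is therefore not independent of the naming. The glycolysis list holds Aldoc, one of the genes that most set the astroglia-like cluster apart. Immediate early genes, which are transcribed within minutes of stimulation or of tissue handling, were higher by 4.38 to 7.09-fold, and single plates spanned 1.94 to 9.76-fold. Cytosolic ribosomal protein genes were lower in astroglia-like cells by 1.78 to 3.01-fold, and heat shock genes by 1.75 to 2.74-fold. Over single plates astroglia-like cells were higher by 2.55 to 6.79-fold for lipogenesis, 2.01 to 3.86-fold for fatty acid oxidation, 1.18 to 2.04-fold for cholesterol synthesis and 1.90 to 5.17-fold for interferon and MHC class I genes. For ribosomal genes the sums were 12712 against 31934 CPM in the Gli1 cells at 5 days and 15274 against 45997 CPM at 12 weeks. Nuclear genes of oxidative phosphorylation were lower by 1.23 to 1.36-fold. In the Gli1 cells at 5 days TMM and median-of-ratios scaling, which put the shift between the classes at -0.40 and -0.38, turned this to log2 ratios of 0.10 and 0.08. Mitochondrially encoded genes were higher by 1.22 to 1.49-fold by group and from 0.922 to 1.501-fold by plate. Cycling cells exceeded neuroblast-like cells in 4 of 4 groups for lipogenesis (1.51 to 3.01-fold), fatty acid oxidation (1.504 to 2.11-fold), glycolysis (1.39 to 1.86-fold) and immediate early genes (2.64 to 5.28-fold). Notch pathway genes were higher by 4.19 to 10.3-fold and Hedgehog pathway genes by 6.90 to 15.9-fold in astroglia-like over neuroblast-like cells (4.03 to 10.3-fold and 6.90 to 42.5-fold by plate).

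**Figure D2:**
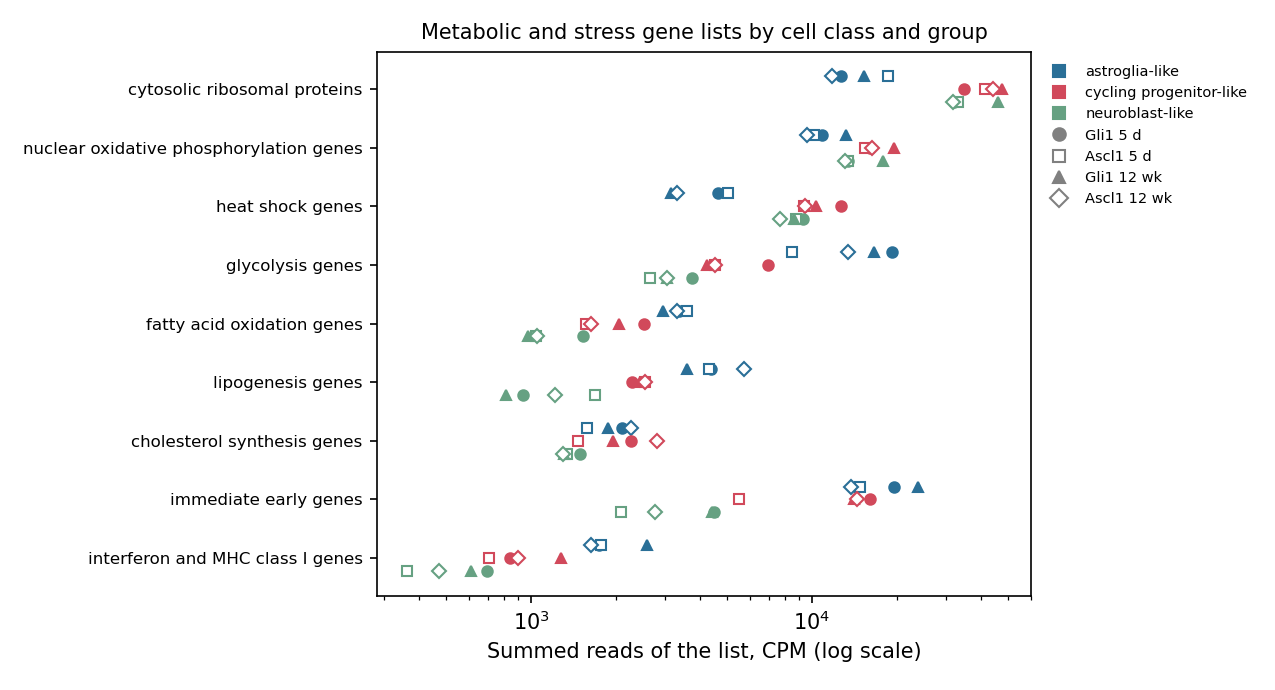
Reads of 9 gene lists summed per class and group, in CPM on a log axis, with colour for the class and marker shape for the group. Glycolysis genes stood at 8517 to 19275 CPM in astroglia-like and at 2660 to 3753 CPM in neuroblast-like cells, and ribosomal protein genes in the opposite order.

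The comparison of Gli1 with Ascl1 cells at 5 days asked how the astroglia-like cells caught by the drivers differed soon after labelling (69 against 10 cells, 29059558 against 1686291 reads). This class holds stem-like cells and astrocytes together. In every comparison of it, a different mix of these cells cannot be told apart from a difference within a cell type. Some genes named below, such as Aqp4, Gjb6 and Wnt8b, were themselves among the markers used to name clusters. Glycolysis genes were higher in the Gli1 cells, with 12 of 15 members higher and a median log2 ratio of 0.91, above 99.7% of random lists matched for expression. Ldha, lactate dehydrogenase (chromosome 7, 46841475 to 46855627, plus strand), stood at 393 against 98.4 CPM and the glycolytic enzyme Pgam1 at 209.4 against 45.1 CPM. Hk1, a hexokinase, was lower (24.98 against 91.3 CPM). Cholesterol synthesis genes were also higher (median 0.70, 10 of 17 members, above 99.6% of random lists), among them the mevalonate pathway enzymes Fdps (125.3 against 18.98 CPM) and Mvd (89.1 CPM against 0 reads, at least 50.1-fold). Hmgcr, the rate-limiting enzyme, and its regulator Srebf2 were lower (log2 ratios of -2.05 and -1.75). Cytosolic ribosomal protein genes were lower in the Gli1 cells, in 46 of 51 members, with a median of -0.66 and 12712 against 18607 CPM in sum. Rpl38 and Rpl32 had the lowest ratios (-1.44 and -1.42) and Rps4x the highest (1.02).

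Genes of quiescence and cycle inhibition had a median of -1.39 (8 of 10 members lower, below all but 0.19% of random lists). Their sum was higher in the Gli1 cells (5545 against 4253 CPM), so median and sum differed in sign. Sparc, a secreted matrix protein (3836 against 1421 CPM), and Hopx (741 against 378 CPM) were higher, and Nfib, a transcription factor of the nuclear factor I family (216.04 against 699.8 CPM), and the ubiquitin ligase gene Huwe1 (log2 ratio -1.81) were lower. Fatty acid oxidation genes had a median of 0.35 (12 of 20 higher, above 97.8% of random lists) and a sum of 3357 against 3575 CPM, again of opposite sign. The carnitine carrier gene Slc25a20 stood at 63.9 against 1.78 CPM, a ratio of 35.9 that rests on 3 Ascl1 reads (interval 12.3 to 174.2). Cpt1a, which admits fatty acids to mitochondria, was lower (log2 ratio -1.12). The other 13 lists lay inside the middle 95% of random lists, among them the Notch (median 0.15), Hedgehog (-0.92), BMP and Id (-1.15) and Wnt (-0.21) lists and the shared astroglial genes, of which 6 were higher and 8 lower.

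By the rule for single genes, the 10 highest in the Gli1 cells all had 0 reads in the 10 Ascl1 cells. They included Slc2a1, the glucose transporter GLUT1 (chromosome 4, 119108711 to 119137983, plus strand), at 243.7 CPM in 32 of 69 cells and at least 136.99-fold higher, and Aqp4 at 232.5 CPM (at least 130.7-fold). Gjb6, an astrocyte connexin, stood at 177.6 CPM (at least 99.8-fold), the Frizzled ligand gene Ndp at 236.9 CPM (log2 ratios of 6.46 and 8.20 by plate), and H2-K1, a classical MHC class I heavy chain, at 181.8 CPM in 40 of 69 cells. Tmem246 (349 CPM, at least 195.9-fold), Lmcd1, Mxra8, the HSP90 cofactor gene Ahsa1 and Chchd3, a protein of mitochondrial cristae, completed them, down to at least 91.995-fold. Among the 10 lowest were Cmya5 (0 reads against 206.4 CPM in 4 of 10 cells, at least 1999-fold lower), Cfd, Ptgfrn, Myo7a, Mrnip, Mtmr4, Elk4, B3glct and Spg11, each read in 3 or 4 of the 10 Ascl1 cells. Myo7a, an unconventional myosin, rested on 1 read in the Gli1 cells, with a ratio of 4601 (interval 819 to 182408). Gli1 itself had a log2 ratio of -0.94 and Ascl1 of 0.67. The median log2 ratio of all 5924 genes at the expression floor was -0.42, and TMM and median-of-ratios scaling put the shift between the groups at -0.45 and -0.41. Under them the ribosomal median was -0.21 and -0.26, and it was -1.66 with classes from single-cell marker scores. Between G5a and G5b the same lists had medians of 0.17 (glycolysis), 0.07 (cholesterol), -0.27 (ribosomal), -0.22 (quiescence) and 0.15 (fatty acid oxidation). With plate AX added to the Ascl1 cells, glycolysis (-0.20), fatty acid oxidation (-0.36) and H2-K1 (-0.96) changed sign, and ribosomal genes (-0.12) and quiescence genes (-0.39) came nearer to 0. Over all comparisons with Ascl1 cells at 5 days, AX moved 38 single-gene ratios by more than 1 in log2, reversed 2 and left 28. In simulated groups of these sizes, drawn without differences between plates, 34.3% of unchanged genes passed the rule for single genes here. From 23.6 to 39.1% did so in the other astroglia-like comparisons. Single genes named in astroglia-like cells are therefore the extremes of small samples of cells.

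At 12 weeks the comparison asked whether astroglia-like cells of the Gli1 and Ascl1 lineages differed (21 against 24 cells, 8935826 against 5108311 reads). Nuclear genes of oxidative phosphorylation were higher in the Gli1 cells, in 39 of 47 members, with a median log2 ratio of 0.68 and 13197 against 9606 CPM. Atp5o and Ndufb3, subunits of ATP synthase and complex I, led (1.52 and 1.48), and Sdha and Ndufs1, catalytic subunits of complexes II and I, were lowest (-1.71 and -1.34). All but 1 of the Ascl1 cells came from A12b, and in neuroblast-like cells A12a of the same group exceeded A12b in this list with a median of 0.52. Interferon and MHC class I genes were higher in 9 of 13 members (median 0.96). They were led by Irf7, a transcription factor induced by interferon (chromosome 7, 141262706 to 141266481, minus strand), at 55.5 against 0.196 CPM, a ratio of 284 on 1 Ascl1 read (interval 50.7 to 11222). Ifit3 was also higher (log2 ratio 1.88) and Stat1 lower (-3.88). Immediate early genes were higher in 13 of 15 members (median 0.90), among them Zfp36, which destabilises inflammatory transcripts (402 against 11.8 CPM), and the nuclear receptor gene Nr4a1 (564 against 55.6 CPM), with Jund lowest (-1.44). All cells of plate G12, the Gli1 group at 12 weeks, also carried reads of microglial genes. C1qa, C1qb and Ctss stood at 9.18, 17.9 and 32.1 CPM in its astroglia-like cells, against 0 reads, 0 reads and 0.222 CPM in those of A12b.

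The BMP and Id, Wnt and lipogenesis lists were lower in the Gli1 cells at 12 weeks. BMP and Id genes had a median of -1.83 (5 of 8 lower), with the receptor gene Bmpr2 at 1.57 against 39.2 CPM and the signal transducer gene Smad5 at 13.9 against 199.7 CPM, while Id2 was higher (319 against 78.3 CPM). The Wnt list had a median of -1.11 (10 of 11 lower, 932 against 1765 CPM), with the co-receptor gene Lrp6 lowest (-3.01) and the secreted antagonist gene Sfrp1 highest (0.59). Lipogenesis genes had a median of -0.98 (9 of 11 lower, 3600.0 against 5742 CPM), with their regulator Srebf1 (chromosome 11, 60199089 to 60222581, minus strand) at 75.9 against 375 CPM and the elongase gene Elovl6 at -1.88. The remaining 12 lists lay inside the middle 95% of random lists, including the shared astroglial (median 0.29), Notch (-0.12) and glycolysis (0.24) lists.

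Single genes higher in the Gli1 cells at 12 weeks were led by Adora2b, an adenosine receptor, at 216.2 CPM in 11 of 21 cells against 0 reads (at least 368-fold). Cdkn1a, the cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand), stood at 64.01 CPM in 6 of 21 cells against 0 reads (at least 108.998-fold), and Psmb10, an immunoproteasome subunit, at 158.5 against 1.17 CPM. Arl4a, the calcium sensor gene Ncald, Creg2, the lysosomal mannosidase gene Man2b1, the sulfide oxidising enzyme gene Sqor, C1qtnf5 and Mfrp followed. C1qtnf5 and Mfrp overlap on chromosome 9 and had the same 449 reads, so which of them was expressed is open. Etnppl, an astrocyte enzyme of phospholipid breakdown (chromosome 3, 130617448 to 130637521, plus strand), was lowest, with 0 reads against 148.6 CPM in 12 of 24 Ascl1 cells (at least 443-fold lower). Cpeb4, a regulator of polyadenylation, was read in 14 of 24 Ascl1 cells and 0 Gli1 cells (at least 253.06-fold). Aak1, Folh1, Ecm2, Cpped1 and the deubiquitinase gene Usp8 also had 0 reads in the Gli1 cells. Yeats2, Ppp2ca, the catalytic subunit of protein phosphatase 2A, and Rnf180 had 1, 1 and 2 reads, with ratios of 1345 (interval 240.7 to 53200), 1305 (233.5 to 51611) and 520.4 (143.4 to 4307). Gli1 and Ascl1 had log2 ratios of -1.40 and -0.44. All 5942 genes at the floor had a median log2 ratio of -0.18, and TMM and median-of-ratios scaling put the shift at -0.28 and -0.28. Plate A12a held only 1 of these cells, and without it the immediate early median was 2.36. That median was also 2.10 without the highest cell of each gene, 1.64 as a mean over cells and 0.13 with AX added. The BMP and Id median was -0.28 at a floor of 50 CPM, -0.67 without a floor, -0.55 with AX added and -0.74 with classes from marker scores, under which Man2b1 turned to -0.41.

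**Figure D3:**
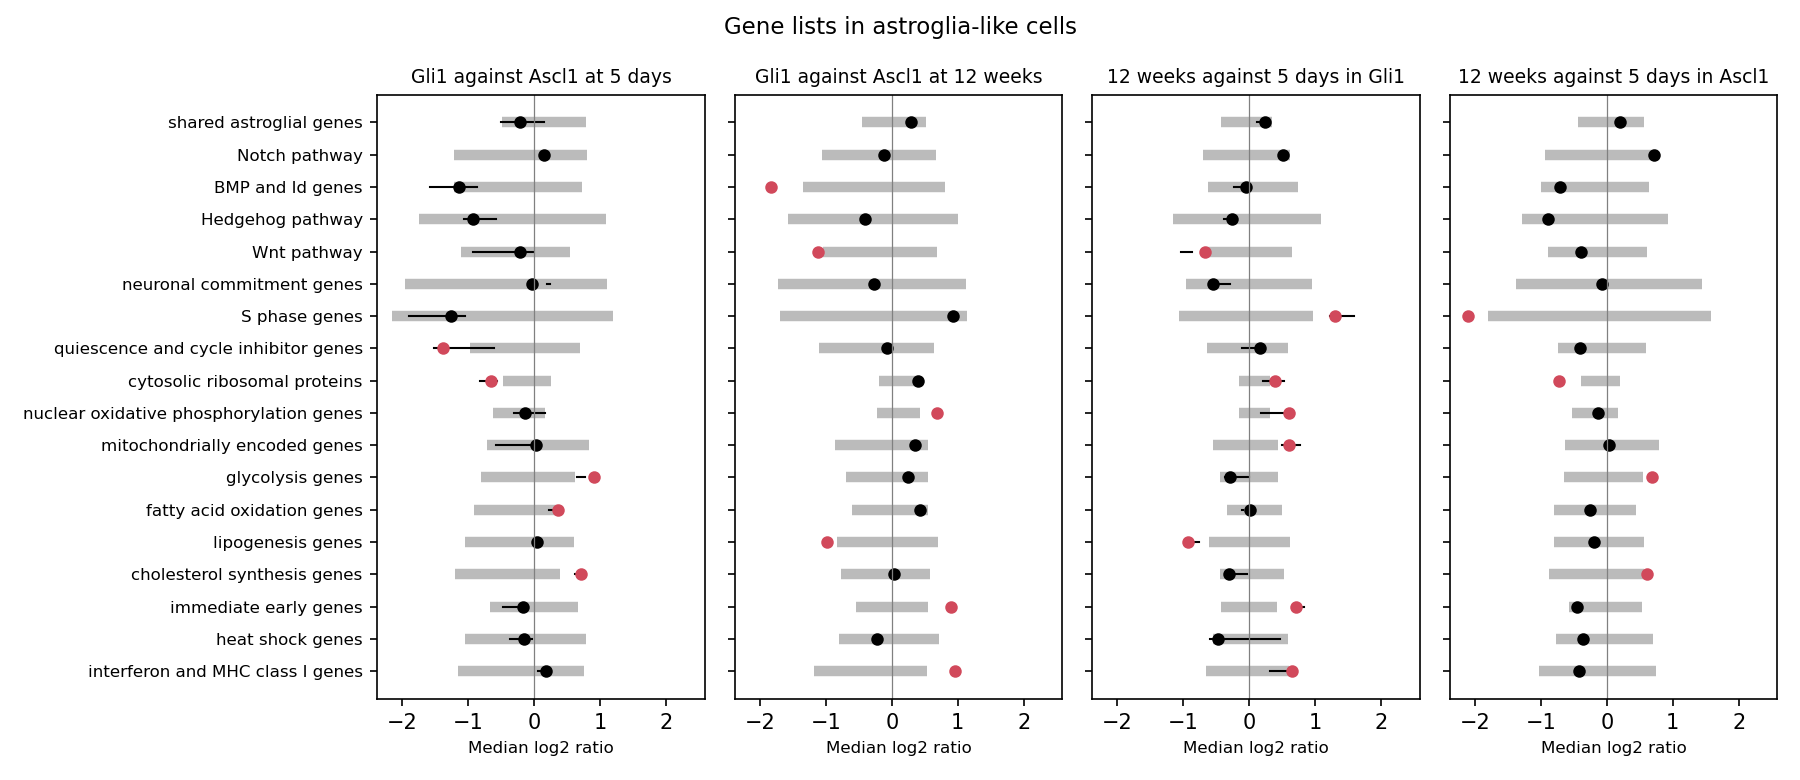
Median log2 ratio of each gene list in astroglia-like cells for the 4 comparisons (dots, red where the list stood outside the middle 95% of 10000 random lists with the same sign in every plate pair), with that range in grey and the plate pairs as black lines. The drivers at 12 weeks and the Ascl1 times had 1 plate pair each, so the sign rule added little there. Ribosomal genes had a median of 0.40 between the times in the Gli1 cells and of -0.72 in the Ascl1 cells.

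Within the Gli1 lineage, the astroglia-like cells at 12 weeks were set against those at 5 days to compare this class between the times (21 against 69 cells, plate G12 against G5a and G5b). Immediate early genes were higher at 12 weeks in 14 of 15 members (median log2 ratio 0.70), with the stress-induced factor Atf3 at 168.9 against 9.02 CPM (log2 ratios of 3.66 and 7.41 by plate) and Nr4a1 at 564 against 72.7 CPM. Nuclear oxidative phosphorylation genes were higher in 39 of 47 members (median 0.60), from Atp5g3 (1.49) to Sdha (-1.60). Ribosomal protein genes were higher in 41 of 51 (median 0.40; Rpl37 1.202, Rpl3 -0.54), and mitochondrially encoded genes in 10 of 13 (median 0.60), led by mt-Co2 at 99.2 against 0.206 CPM. Interferon and MHC class I genes were higher in 9 of 11 members (median 0.65), with Irf7 at 55.5 against 2.79 CPM (log2 ratios of 3.56 and 5.65 by plate) and the antiviral membrane protein gene Bst2 at 56.96 against 19.1 CPM (0.58 and 2.15). The microglial genes C1qa, C1qb and Ctss stood at 9.18, 17.9 and 32.1 CPM in the G12 cells, against 0.0474, 0 and 0.0474 CPM in G5a and 0 reads in G5b. S phase genes were higher in 3 of 4 members (median 1.29). These were the histone mRNA binding protein gene Slbp (107.9 against 37.5 CPM), the helicase gene Mcm7 (113.4 against 40.8 CPM) and the replication clamp gene Pcna (141.5 against 63.9 CPM), while Rpa2 was lower (-2.20). Of these 21 cells, 0 had a thinned read of Mki67 or Top2a.

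Wnt pathway genes were lower at 12 weeks in 9 of 11 members (median -0.68, 932 against 1901 CPM). Wnt8b, a ligand expressed by dentate stem cells (chromosome 19, 44493472 to 44514273, plus strand), had 0 reads against 90.2 CPM in 18 of 69 cells (at least 269-fold lower). Frzb, a secreted Wnt antagonist, stood at 82.6 against 411 CPM, while Ctnnb1, beta-catenin, was higher (0.46). Lipogenesis genes were lower in 7 of 9 members (median -0.93), with Elovl6 at 8.51 against 91.1 CPM and Srebf1 at 75.9 against 171.5 CPM, but Thrsp, a lipogenic protein of dentate stem cells, differed little (2410 against 2170 CPM).

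Cdkn1a headed the single genes higher at 12 weeks (64.01 against 0.413 CPM). Ctss, a cathepsin of microglia, was read in 21 of 21 cells at 32.1 CPM against 1 read (ratio 933, interval 166.2 to 36992) and belonged to the microglial genes read throughout plate G12. Carmil1 (917, 163.3 to 36349) and the nucleoside transporter gene Slc29a3 (203.8, 68.7 to 997) also stood against 1 and 3 reads, and Shisa5, a p53 target, had 979 against 76.4 CPM. Tbc1d5, Ctnna2, Atf3, Irf7 and Eif4enif1 completed the 10, down to a log2 ratio of 3.59. Besides Wnt8b, the lowest were Otx1, a homeodomain transcription factor (chromosome 11, 21994764 to 22002897, minus strand; 0.336 against 77.9 CPM, read in 29 of 69 cells at 5 days, ratio 231.96, 79.3 to 1126) and the nucleotidase gene Nt5c2 (0.671 against 182.6 CPM). The nuclear import gene Ipo13 (ratio 629.8, 112.9 to 24886), the sodium pump regulator gene Fxyd6 (220.6, 75.4 to 1070.5), the interferon receptor gene Ifnar1 (191.6, 65.5 to 929.8), the mitotic regulator gene Fzr1 and the RNA-binding protein gene Caprin1 followed. The myelin genes Pllp (-5.91 and -3.39 against the single plates) and Mbp (8.84 against 417 CPM; -5.85 and -1.45) were also among them, and 98.6% of the oligodendrocyte marker reads in the astroglia-like cells of G5a came from 1 cell. Ascl1 had a log2 ratio of -1.44 and Gli1 of 0.97. The median of all 5042 genes at the floor was 0.04, with shifts of -0.09 and -0.14 by TMM and median-of-ratios scaling. Against G5a and G5b taken singly the medians ran from 0.18 to 0.68 (oxidative phosphorylation), 0.21 to 0.52 (ribosomal), 0.50 to 0.76 (mitochondrial), 0.71 to 0.83 (immediate early), 0.31 to 0.57 (interferon and MHC class I), 1.22 to 1.60 (S phase), -1.03 to -0.87 (Wnt) and -0.94 to -0.77 (lipogenesis). Between G5a and G5b the first 3 lists had medians of -0.44, -0.27 and 0.62, outside their random ranges. The oxidative phosphorylation median of 0.18 was that without G5a and was 0.34 as a mean over cells, the S phase median was 0.02 without an expression floor, and the Wnt median was -1.44 without the highest cell of each gene. Y-linked genes were read in 51.9% of all Gli1 cells at 5 days and 7.53% at 12 weeks, so the share of cells with such reads also differed between the groups.

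The same comparison within the Ascl1 lineage set 24 astroglia-like cells at 12 weeks against 10 at 5 days. Ribosomal protein genes were lower at 12 weeks in 47 of 51 members (median log2 ratio -0.72, 11755 against 18607 CPM), led by Rps8 (-1.40) and Rpl15 (-1.30), with Rpl30 highest (0.58). Glycolysis genes were higher in 12 of 15 members (median 0.68, 13439 against 8517 CPM). Eno2, an enolase, stood at 76.4 CPM against 0 reads (at least 42.9-fold) and Ldhb at 695 against 275 CPM, while Hk1 was lower (-1.21). Cholesterol synthesis genes were higher in 11 of 17 members (median 0.62), with Fdps at 209.7 against 18.98 CPM, Mvk at 2.49 and Nsdhl lowest (-0.999). S phase genes had a median of -2.11 (4 of 5 lower), with the helicase genes Mcm6 (9.98 against 87.8 CPM) and Cdc45 (-2.72) lowest and Pcna higher (1.44). The other 14 lists lay inside the middle 95% of random lists, including the Notch list at 0.72 and the BMP and Id list at -0.71.

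Among single genes, Gjb6 was read in 12 of 24 cells at 303 CPM at 12 weeks against 0 reads at 5 days (at least 170.4-fold). H2-K1 was read in 15 of 24 at 187.9 CPM (at least 105.6-fold) and Etnppl in 12 of 24 at 148.6 CPM (at least 83.5-fold). Slc2a1 was read in 7 of 24 at 215.7 CPM (at least 121.3-fold in reads). Its log2 ratio was 7.76, and 6.197 without the 1 cell of A12a. Most cells at 12 weeks had no Slc2a1 read either, so its absence from 10 cells at 5 days need not be a difference. Paqr7, a membrane progestin receptor, Hsd11b1, which activates glucocorticoids, and Rtfdc1 also had 0 reads at 5 days, while Sh3bgrl3 stood at 2271 against 10.7 CPM. Atp1b3, a sodium pump subunit, and St8sia2, a polysialyltransferase, stood against 1 read each, with ratios of 525 (interval 94.1 to 20744) and 439 (78.7 to 17354). Of the 10 lowest, Mtg2, a GTPase of mitochondrial ribosomes, was read in 8 of 10 cells at 5 days (348 against 0.783 CPM), and Mdp1 in 7 of 10 (152.999 against 0.196 CPM on 1 read, ratio 782, 139.04 to 30988). Fxyd6 (at least 335-fold), Myo7a (at least 269.6-fold), Wdr4, Tut1 and Wwc2 had 0 reads at 12 weeks. Cluh, which binds mRNAs of mitochondrial proteins, and Psd2 had 1 read each, with ratios of 866 (154.3 to 34339) and 715 (127.1 to 28356). Gli1 and Ascl1 had log2 ratios of 1.44 and -0.34. All 6413 genes at the floor had a median of -0.15, with shifts of -0.21 and -0.19 by TMM and median-of-ratios scaling. With plate AX added to the cells at 5 days, glycolysis (-0.36) and H2-K1 (-0.91) changed sign and the ribosomal median was -0.20. Y-linked genes were read in 45.6% of all Ascl1 cells at 5 days and in 1.72% at 12 weeks, and each time point had 1 plate with at least 10 of these cells, so plate and time cannot be told apart.

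Neuroblast-like cells, the common product of both drivers, were compared in the same way with larger numbers of cells. Those of A5 and A12b fell largely into clusters that these plates shared, and most of those of G12 into another cluster, which held 0 cells of G5a and 2 of G5b. Plate A12a, of the same group as A12b, lay closer to G12 (median absolute log2 ratio 0.465) than to A12b (0.614). The comparison at 5 days sets A5 against G5a and G5b, so driver and plate cannot be told apart in it. Eomes was among the top genes of a neuroblast-like cluster with 59 cells of A5, 30 of A12b and 1 of G12. The other plates of the groups had 0 cells in that cluster. Some commitment genes, such as Dcx, Eomes and Neurod1, were also among the neuroblast markers used to name clusters. In every comparison of neuroblast-like cells, a different mix of cells cannot be told apart from a difference within a cell type. At 5 days the question was again how the drivers differed early, now in their neuronal progeny (43 Gli1 cells against a larger number of Ascl1 cells). Immediate early genes were higher in the Gli1 cells in 7 of 9 members (median log2 ratio 1.12), with Fos at 1535 against 304 CPM and Jun at 586 against 124.8 CPM. Lipogenesis genes were lower in 8 of 10 members (median -1.21), with the fatty acid synthase gene Fasn (chromosome 11, 120805846 to 120824547, minus strand) at 40.5 against 261.8 CPM and the acetyl-CoA carboxylase gene Acaca at 24.4 against 141.5 CPM. Neuronal commitment genes were lower in 9 of 13 members (median -0.36), with Dcx at 243.2 against 851 CPM and the neuroendocrine factor Insm1 at -1.99. Tubb3, neuronal tubulin, was higher (3649 against 1871 CPM). Quiescence and cycle inhibitor genes were lower in 8 of 9 (median -0.89), with the retinoblastoma gene Rb1 at -3.77. Fatty acid oxidation genes were higher in 8 of 12 (median 0.65), with Acads at 1.77. By the rule for single genes, H2-D1, a classical MHC class I heavy chain (424 against 69.8 CPM), the nuclear envelope gene Emd, Slc2a1, Naga and Zfp983 were highest (log2 ratios of 2.52 to 2.603). By plate they ran from 1.85 to 2.98 for H2-D1, 2.02 to 2.94 for Emd, 0.67 to 3.20 for Slc2a1, 1.43 to 3.02 for Naga and 2.02 to 2.90 for Zfp983. The axon guidance gene Sema5a (0.322 against 171.9 CPM), Galnt17 (0 reads, at least 494-fold lower), Adamts18, Abcc8 and C2cd3 were lowest. The shift between the groups was -0.21 by TMM and -0.23 by median-of-ratios scaling. Against G5a and G5b singly the medians ran from 0.84 to 1.32 (immediate early), -1.30 to -1.09 (lipogenesis), -0.52 to -0.47 (commitment), -1.12 to -0.69 (quiescence) and 0.01 to 0.91 (fatty acid oxidation). Between G5a and G5b immediate early and fatty acid oxidation genes themselves had medians of 0.54 and 0.84, and with AX added to the Ascl1 cells the immediate early median was 0.37.

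At 12 weeks neuroblast-like cells of both lineages were numerous, and their comparison asked whether they differed between the drivers. Ribosomal protein genes were higher in the Gli1 cells in 49 of 51 members (median 0.57, 45997 against 31729 CPM), with Rps19 at 1321 against 774 CPM and Rps2 lowest (-1.07). Nuclear oxidative phosphorylation genes were higher in 43 of 47 members (median 0.49; Ndufb10 0.93, Sdha -0.68). Commitment genes were lower in 10 of 12 members (median -0.56), with Dcx at 198.3 against 511 CPM (-1.81 and -0.29 by plate) and Eomes, a transcription factor of intermediate progenitors, at 45.3 against 130 CPM (-1.97 and -0.36). Wnt genes were lower in 5 of 6 (median -0.94; Ctnnb1 167.3 against 492 CPM). BMP and Id genes were lower in 3 of 4 (median -1.15; Smad1 -2.28, Id2 0.42), although their sum was slightly higher (1222 against 1148 CPM). The 3 interferon and MHC class I genes at the floor were higher (median 0.88), with B2m, the light chain of MHC class I, at 118.8 against 64.2 CPM and read in every Gli1 cell. The same cells carried the microglial genes C1qa, C1qb and Ctss at 10.3, 16.2 and 29.4 CPM, against 2.01, 4.42 and 7.23 CPM in A12a and 0, 0 and 0.0403 CPM in A12b, whereas Csf1r was lower than in A12b (13.6 against 23.2 CPM). Pnp.1, a purine nucleoside phosphorylase gene, the chemokine gene Ccl2 (40.8 against 0.261 CPM), the vitamin K enzyme gene Vkorc1 (996 against 70.8 CPM), Timp4 and Ctss were the highest single genes. Poldip3 (74.7 against 1829.8 CPM), the presynaptic scaffold gene Bsn, Irgq, Tbl1xr1 and Pygb were the lowest. Against the single Ascl1 plates the log2 ratios were -5.83 and -0.37 for Poldip3, -4.54 and -0.40 for Bsn, -4.24 and -0.38 for Tbl1xr1 and 1.88 and 4.87 for Ctss, so those of Poldip3, Bsn and Tbl1xr1 rested mostly on 1 plate. Pnp.1 (5.34 and 7.28), Ccl2 (4.73 and 5.33), Vkorc1 (3.79 and 3.80), Timp4 (3.29 and 3.47), Irgq (-4.36 and -1.195) and Pygb (-3.90 and -2.44) stood apart from both. The shift was -0.21 by either scaling. Without A12a and A12b in turn the ribosomal median was 0.70 and 0.31 and the oxidative phosphorylation median 0.77 and 0.18. A12a itself exceeded A12b with a median of 0.52 for oxidative phosphorylation. For ribosomal genes it did so with a median of 0.42, inside the random range of 0.22 to 0.45. For the Wnt and the BMP and Id lists A12a against A12b had medians of -0.75 and -0.71, inside their random ranges but near in size to the medians between the drivers.

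Neuroblast-like Gli1 cells at 12 weeks were set against the 43 such cells at 5 days to compare this class between the times, although most cells of the times lay in different clusters. Ribosomal protein genes were higher at 12 weeks (47 of 51, median 0.57; Rpl38 395 against 170.8 CPM), as were nuclear oxidative phosphorylation genes (39 of 47, median 0.59; Ndufa4 1.22). Fatty acid oxidation genes were lower (8 of 12, median -0.63; Acads 7.11 against 54.6 CPM). Their 3 interferon and MHC class I genes had a median of 1.31, with B2m at 118.8 against 25.002 CPM, H2-K1 at the median (0.20 and 4.796 by plate) but H2-D1 at -0.51, which left the sum lower at 12 weeks (609.6 against 694 CPM). The microglial genes C1qa, C1qb and Ctss, at 10.3, 16.2 and 29.4 CPM in these G12 cells, stood at 0.115, 0 and 0.115 CPM in G5a and had 0 reads in G5b. Gal, the neuropeptide galanin (chromosome 19, 3409915 to 3414544, minus strand), was read in 43 cells at 202.7 CPM at 12 weeks against 0 of 43 at 5 days (at least 1048-fold). Pnp.1, Sema5a, Adamts18 and Ccl2 were the other highest genes, and Zfp41, Zfand2a, Pygb, Pcid2 and Scaper the lowest (log2 ratios of -4.16 to -2.84). By plate Scaper stood at -3.58 and -0.15, Zfand2a at -3.59 and -1.60 and Pcid2 at -3.44 and -1.67. The plate pairs ran from 0.44 to 0.69 (ribosomal), 0.37 to 0.93 (oxidative phosphorylation), -0.86 to -0.31 (fatty acid oxidation) and 0.22 to 1.65 (interferon and MHC class I, 0.22 without G5a). Between G5a and G5b ribosomal and oxidative phosphorylation genes had medians of -0.26 and -0.51.

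In the Ascl1 lineage the neuroblast-like cells at 12 weeks had lower commitment genes than those at 5 days, in 10 of 13 members (median -0.48), with Eomes at 130 against 345 CPM and Insm1 at -1.45 (-5.24 and -0.73 by plate). Lipogenesis genes were lower in 7 of 10 (median -0.56), with Acaca at 52.7 against 141.5 CPM. Immediate early genes were higher in 7 of 9 (median 0.66; Fos 630 against 304 CPM, Klf6 1.02), and interferon and MHC class I genes in 3 of 4 (median 0.80; H2-D1 227.5 against 69.8 CPM). Selenop, which transports selenium (95.8 against 1.47 CPM), Prn, Rgmb, the acid ceramidase gene Asah1 and the nuclear lamin gene Lmna were highest, and Wwc1, Cmas, Foxk2, Hist1h2bf and Srrd lowest (log2 ratios of -2.69 to -2.03). By plate Selenop stood at 1.18 and 6.02, Cmas at -5.90 and -1.62 and Foxk2 at -5.97 and -1.35. Against A12a and A12b singly the medians ran from -0.55 to -0.28 (commitment), -0.97 to -0.18 (lipogenesis), 0.43 to 0.46 (immediate early) and 0.47 to 1.08 (interferon and MHC class I). With AX added to the cells at 5 days the first 3 medians were -0.21, -0.18 and 0.10.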

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

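Tests of gene length and sequencing depth were set out beforehand, and all other tests described here were chosen only after the result had been seen.

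S phase genes of astroglia-like cells had medians of opposite sign in the drivers when 12 weeks was compared with 5 days. Their median log2 ratio was 1.29 in the Gli1 cells, with the same sign in both plate pairs, and -2.11 in the Ascl1 cells, in the 1 plate pair with enough cells. The members at the expression floor were 4 and 5 and not the same, Pcna was higher at 12 weeks in both (1.13 and 1.44), and without a floor the Gli1 median was 0.0166. Cytosolic ribosomal proteins went apart in the same way, with medians of 0.40 and -0.72. For either list the difference was not tested, because no label names an animal and each group therefore counted as 1 sample. Both Ascl1 values rest on the 10 astroglia-like cells of plate A5.

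Plate AX, which joined no group, held cells with reads of Mki67 or Top2a after thinning. They were 12.9% of its cells (interval 9.09 to 17.5%), and against the groups the difference was not tested. Among its cycling progenitor-like cells the share was 57.4%, and among its neuroblast-like cells 1.10%.

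Neuroblast-like cells of A12b lay closer to those of A5 than to those of A12a of the same group, with a median absolute log2 ratio at 40 cells per plate that was 1.31 times as large between A12a and A12b as between A12b and A5. The ratio between A12a and A12b was also 1.32 times that between A12a and G12, which argues against a difference between the driver lines as the cause, and 85.8% of it stayed after correction for gene length. The length test was taken on the whole ratio between A12a and A12b (0.614), and A12b and A5 already differed by 0.469. A length bias behind the excess alone would leave most of that whole ratio, so the test cannot decide on gene length. After thinning to 50000 reads, 100.5% of the excess over the ratio between A12b and A5 stayed, which argues against sequencing depth. A difference between library batches cannot be told apart from the pattern, since its prediction and the pattern are the same distances. Titles of A5 and A12b carry dates of 1 year, that of G12 of the year before, and A12a carries none. G5b, dated in the same year as A5, had 0 cells in the clusters that held most neuroblast-like cells of A5 and A12b. G5b had 16 cells in a further neuroblast-like cluster, with 4 of A5 and 10 of A12b. Y-linked genes were read in 45.6% of all cells of A5, 0% of A12b and 7.02% of A12a. In this share A12b was nearer to A12a than to A5, which argues against the sex of the mice as the cause. The meaning of the dates and the mice behind each plate, with their litter, stay open and untested.

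Myelin transcripts (oligodendrocyte markers) stood at 2531 CPM in the astroglia-like cells of G5a. In this class 98.6% of the reads came from 1 cell, and without it 1.44% of the level was kept, 36.4 CPM. Oligodendrocyte RNA spread over the plate is therefore argued against as the main source, although Mbp was read in 55 of 55 cells of G5a and 6 of 80 of G5b at a low level (median 13.9 CPM in G5a). That cell may be a doublet or a misplaced oligodendrocyte, which was not tested. With the highest cell of each gene left out of both groups, Mbp and Pllp had log2 ratios of -4.34 and -2.22 between 12 weeks and 5 days in the Gli1 cells. The cells at 12 weeks thereby also lost their own highest cell. These ratios therefore cannot show how much of the difference would stay without the G5a cell alone.

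Microglial genes (C1qa, C1qb, Ctss, Csf1r, Cx3cr1) were read in every cell of G12 at 73.7 CPM. Their highest level among the 3 classes was 1.22 times the lowest (79.3 CPM in astroglia-like and 65.3 CPM in cycling cells), which is consistent with microglial RNA spread over the whole plate. The 3 highest cells held 9.51% of the reads, which argues against a few microglia inside the classes. Interferon and MHC class I genes and Ctss were higher in the same plate and may in part share this source, which was not tested. No biological explanation was tested, since G12 is the only plate of its group.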

How the results depend on the processing

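Names not centred within plates, granule neuron-like clusters kept apart, leaving out the highest cell of each gene, the reduced total, both scalings between classes and the settings for neuroblast-like cells were chosen after seeing the data, and all other alternatives before the data were examined. No paired analysis was possible because no cell was tied to a mouse. Keeping all deposited cells changed nothing, since 0 cells had fewer than 1000 genes. A value was counted as moved when a share left its interval, a list median shifted by more than 0.5 times the width of its random range, a single gene by more than 1 or a ratio between classes by more than 0.5 in log2. Of the called list medians, 330 values stayed, 32 moved and 3 reversed. Of class shares 91 stayed and 19 moved, of cycle shares 10 and 4, and of log2 ratios between classes 2 moved, 2 reversed and the others stayed. Medians that were not called stayed in 581 values and moved in 28, and single genes stayed in 1072, reversed in 3 and moved in the others. For single genes of astroglia-like cells a pseudocount of 5 CPM moved 74 values and left 13. Classes from marker scores moved 42 and left 44, and leaving out the highest cell of each gene moved 30 and left 57. For every change given here the cause was not tested.

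Adding AX to the Ascl1 cells at 5 days reversed glycolysis (-0.20), fatty acid oxidation (-0.36) and H2-K1 (-0.96) against Gli1, and glycolysis (-0.36) and H2-K1 (-0.91) between the Ascl1 times. It moved ribosomal genes to -0.12 and -0.20 in these comparisons, quiescence genes to -0.39 and the cycle share to 18.4%. In neuroblast-like cells it moved immediate early genes to 0.37 (against Gli1) and 0.10 (between times), lipogenesis to -0.18 and commitment to -0.21. Added to the Ascl1 cells at 12 weeks, AX moved BMP and Id genes to -0.55, immediate early genes to 0.13, the cycle share to 8.65%, and ribosomal and oxidative phosphorylation genes of neuroblast-like cells to 0.88 and 0.81.

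Classes from the marker score of each cell reversed Man2b1 at 12 weeks (-0.41) and moved BMP and Id genes to -0.74 and ribosomal genes at 5 days to -1.66. Shares became, for Gli1 and Ascl1, 7.41 and 17.3% cycling and 23.7 and 59.5% neuroblast-like at 5 days, and 3.76 and 3.00% cycling and 0.538 and 51.5% neuroblast-like at 12 weeks, with 6.45% astroglia-like for Gli1. Names not centred within plates gave 12.9 and 67.8% neuroblast-like at 12 weeks, where the cluster that held most G12 cells was named microglia-like. Clusters named granule neuron-like at resolution 2 or with variable genes over all cells were joined to neuroblast-like ones in those shares. Kept apart at resolution 2 they left 43.04% (Ascl1, 5 days), 26.9% (Gli1, 12 weeks) and 41.6% (Ascl1, 12 weeks) neuroblast-like, and with variable genes over all cells 27.8% and 39.5% (Ascl1, 5 days and 12 weeks).

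TMM scaling moved ribosomal genes at 5 days to -0.21 and, in neuroblast-like cells at 12 weeks, ribosomal and oxidative phosphorylation genes to 0.78 and 0.70. It reversed oxidative phosphorylation between astroglia-like and neuroblast-like Gli1 cells at 5 days (0.10), as did median-of-ratios scaling (0.0776), which also moved ribosomal genes at 5 days to -0.26. As a mean over cells, immediate early genes at 12 weeks were at 1.64, oxidative phosphorylation between Gli1 times at 0.34, and between classes immediate early genes at 1.73 (Ascl1, 12 weeks) and interferon and MHC genes at 1.91 (Gli1, 5 days).

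A floor of 50 CPM moved BMP and Id genes at 12 weeks to -0.28. Without a floor they were at -0.67, and S phase genes between Gli1 times at 0.0166. Without the highest cell of each gene, Wnt genes between Gli1 times were at -1.44 and immediate early genes at 12 weeks at 2.10. Without thinning the Gli1 cycle share at 12 weeks was 8.60%, and with 2 reads or more 1.61%.

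Fewer plates also moved values. Without G5a, oxidative phosphorylation between Gli1 times was at 0.18, and interferon and MHC genes of neuroblast-like cells at 0.22. Without G5b, Gli1 shares at 5 days were 60% astroglia-like and 23.6% neuroblast-like. Without A12a, immediate early genes at 12 weeks were at 2.36 and, in neuroblast-like cells, ribosomal and oxidative phosphorylation genes at 0.70 and 0.77. Without A12b these were at 0.31 and 0.18, lipogenesis between Ascl1 times at -0.97 and the astroglia-like share at 1.75%. Astroglia-like comparisons without A12b (1 cell left) and neuroblast-like ones without G5b (13 cells left) could not be run.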

Other observations

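No test described here was set out beforehand, and the values are descriptions. Markers of granule neurons were split within the neuroblast-like class. Snap25, a synaptic vesicle fusion protein, was read in 87.4% of these cells at 328 CPM and Rbfox3, the neuronal nuclear antigen, in 87.4% at 342 CPM. Syt1, the calcium sensor of synaptic vesicles, was read in 19.4% at 32.3 CPM, Camk4 in 8.33% and Calb1 in 2.54%. Kcnip3, listed as a granule neuron marker, was highest in astroglia-like cells (63.7% of cells, 274.8 CPM) and lower in neuroblast-like cells (17.8%, 40.2 CPM), as was Fxyd7 (18.9 against 0.0911 CPM).

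GABAergic genes were rare. Gad2, an enzyme of GABA synthesis, was read in 6.45% of cycling progenitor-like cells at 21.8 CPM and in 0.706% of neuroblast-like cells at 0.241 CPM. The vesicular GABA transporter gene Slc32a1 had 0 reads in astroglia-like and neuroblast-like cells. Among markers of other cell types, Cldn5 of endothelial cells was read in 32.9, 32.3 and 44.5% of astroglia-like, cycling and neuroblast-like cells, but at 2.46, 3.64 and 4.196 CPM. Kcnj8 of mural cells and Kl of the choroid plexus had 0 reads in these classes.

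Plate AX held 8.33% astroglia-like cells (5.30 to 12.3%), 20.5% cycling progenitor-like cells (15.8 to 25.8%), 68.6% neuroblast-like cells (62.6 to 74.1%) and 2.65% unnamed cells. In its 22 astroglia-like cells the stem markers summed to 5473 CPM, against 3256 to 3741 CPM in the groups, glycolysis genes to 21345 CPM, immediate early genes to 39667 CPM and ribosomal protein genes to 13156 CPM. Gli1 was read in 13.6% of them (2.91 to 34.9%) and Ascl1 in 77.3% (54.6 to 92.2%). At 40 neuroblast-like cells per plate, the median absolute log2 ratio of AX was 0.803 against A5, 0.769 against A12b, 0.717 against G12 and 0.619 against A12a. The 5 microglial genes were read in 92.4% of its cells at 16.7 CPM.

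Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were found in 87.5% of the cells of G5b, 75.8% of AX, 45.6% of A5, 7.53% of G12 and 7.02% of A12a. No cell of G5a or A12b had one, which allows shares of up to 5.45% and 1.70%. The plates of Gli1 at 5 days thus differed in this share, and no sex is given for the mice of a plate.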
